A study of Mus musculus with 4 samples.

How the data were processed

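CD11b+ cells from mouse spleen were profiled on 4 Affymetrix MOE430 2.0 arrays, a single-colour platform on which a gene is read by 1 or more probe sets. CD11b is the integrin alpha M chain, encoded by Itgam and carried by neutrophils, monocytes, macrophages and some dendritic cells, NK cells and B cells. Per the labels, each array held the RNA of 5 mice, with 2 pools from mice exposed repeatedly to social threat and 2 pools from control mice. Groups and pool numbers were taken from the sample labels, and no label gave a batch, a day or the sex of the mice.

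The deposited values are log2 expression per probe set, made with RMA per the submitters' processing notes, which name no version. RMA corrects background, brings the arrays to a common distribution and summarises the probes of each probe set on the log2 scale. It compresses differences of dim probe sets and gives no detection calls, so a level near the median of an array cannot be separated from background here. The deposited values ran from 2.26 to 14.25, and the medians of the 4 arrays lay between 4.41 and 4.43. No further normalization was applied. Scanner files were not used here. The precision was limited by the number of arrays. The p-value of a single probe set rests on the spread between 2 pools per group, moderated by that of the other probe sets. The main p-values of gene lists, described below, compare a list with other genes, and the permutation p-values compare genes with genes. None of them measures the spread between mice. The order in which the arrays were processed is not given in the sources used here, so a processing batch that followed the groups cannot be told apart from social threat.

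Probe sets were named through the platform annotation supplied for the table. Of 45037 probe sets, 34945 had exactly 1 gene symbol, 932 had several and 9160 were not listed and stayed unnamed. Entrez identifiers of 34741 probe sets matched RefSeq genes of the GRCm38.p6 assembly, which changed 0 symbols. The sources used here name no genome build for the arrays, and coordinates were therefore not printed. For gene lists, each of 18193 genes was represented by its probe set with the highest mean over the 4 arrays. Of these, 9010 genes had more than 1 probe set. Probe sets with several symbols named no gene, which left the beta globin genes outside the erythroid list. The alpha globin gene Hba-a1 was read there only by a dim probe set of its own.

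Social threat was compared with control in R 4.3.3 with limma 3.58.1, using lmFit with 1 term for social threat minus control and eBayes with a mean-variance trend. The residual degrees of freedom were 2 and the prior degrees of freedom 7.1. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over 45037 probe sets, and a probe set was called at an adjusted p under 0.05. The words rose and fell are used of called probe sets only. A size rule without a test counted probe sets that differed by at least 1.5-fold with no overlap between the pools of the groups, beside the same count under the other ways of splitting the arrays, each of which mixes the groups. With 2 pools per group, chance leaves 33.3% of probe sets without overlap.

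Before the data were examined, 36 gene lists were fixed: 17 lists of cell type markers, among them lymphoid, erythroid, platelet and stromal cells, 17 functional lists, and the ribosomal protein and respiratory chain families by symbol. Of 573 symbols in the fixed lists, 516 were measured by a probe set of their own. Lists were tested with camera from limma at a preset correlation of 0.01 between genes, which compares a list with all other genes, and adjusted by Benjamini-Hochberg over 36 lists. Camera called 21 lists, and with a correlation estimated for each list it called 0 of them. That setting also weakened a list simulated without correlation, so it is not a check of correlation alone. For each list the members called over all probe sets are given, with the count adjusted over the list alone beside it.

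Named genes followed a rule fixed at the same time. It took the 12 called genes with the largest rise and the 12 with the largest fall, each by its probe set with the smallest p, and up to 4 members of each list, called members first. It also took Itgam, Nr3c1, Fkbp5, Il1b, Tnf and Il6 whatever their values. A further gene of the rule is not reported here. A planned comparison of the 3 prime and 5 prime control probe sets, a measure of RNA integrity, was not analysed here, since the table held 0 control probe sets of that kind.

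The code was tested on simulated data with known answers. For the comparison of social threat with control, 200 of 45037 simulated probe sets were changed. Of those, 58 of 64 were recovered at 1.5-fold (90.6%), 71 of 71 at 2-fold and 65 of 65 at 4-fold, and 11.8% of the calls in that run were false. Over 20 further draws with the fold sizes mixed, 5.4% of calls were false and 78.2% of changed probe sets recovered when the simulated variances followed the fitted prior. With the moderated variance of each probe set from the fit, which the first run also used, 12.1% of calls were false and 95.2% of changed probe sets recovered. With no probe set changed, 3 were called. Camera recovered a shifted list among 36 and called 0 others. The simulated genes were drawn independently of each other, so this cannot show how the preset correlation fares with correlated genes. In the data the estimated correlation of a list reached 0.443. There 15.8% of probe sets were called, a far larger share than was changed in the simulation.

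Alternatives fixed before the data were examined were eBayes without a trend or in its robust form, a filter on dim probe sets and 1 probe set per gene. They also included the mean of all probe sets of a gene, quantile normalization once more, median centring, array weights, the pool number as a block, other thresholds and the omission of each pool in turn. For the lists, camera with an estimated correlation, camera on ranks and the rotation test fry were also run.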

Results

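Gene expression was measured in CD11b+ splenocytes of mice exposed repeatedly to social threat and of control mice, with 2 pools of 5 mice in each group and 1 array per pool. Each array gave log2 expression for 45037 probe sets. The pools of a group resembled each other more than they resembled the other group. Across probe sets, Pearson's r was 0.9966 between the control pools, 0.9981 between the social threat pools and between 0.9894 and 0.9904 for pools of different groups. The SD of the log2 difference was 0.199 between control pools, 0.150 between social threat pools and at least 0.332 between groups. The arrays shared at most 0.48% of identical values in any pairing, so no array was a copy of another. Levels of the brighter probe set of the Y-linked gene Eif2s3y lay between 9.40 and 9.57 in all 4 pools and no probe set of Xist, the RNA of the inactive X chromosome, exceeded 4.22, with no call for either gene. Group levels below are means ± SD of 2 pools, and log2 fold changes are social threat minus control with their SE.

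The comparison asked which genes differed in CD11b+ spleen cells after repeated social threat. All 19 measured genes of immature neutrophil granules rose, as did 31 of 33 cell cycle genes and 10 of 15 erythroid genes, lists called by camera but with adjusted p = 0.126, 0.112 and 0.112 with an estimated correlation. Conventional dendritic cell markers fell for 10 of 12 genes, B cell markers for 14 of 16, T cell markers for 11 of 13 and NK cell markers for 9 of 14. These lists were called too, with adjusted p = 0.112 with an estimated correlation for each but the NK cell list (0.126). MHC class II genes fell for 14 of 15, immediate early genes for 18 of 19 and cytokine and chemokine genes for 16 of 24, each list with adjusted p = 0.112 with an estimated correlation. Mpo, the myeloperoxidase of azurophilic granules, rose from 6.10 ± 0.18 to 10.95 ± 0.09, a 28.9-fold difference. Cd209a, a C-type lectin of dendritic cells, fell from 9.66 ± 0.10 to 7.66 ± 0.01, a 3.99-fold difference.

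In limma, 7099 of 45037 probe sets (15.8%) were called, 3194 higher and 3905 lower in social threat. They represented 1927 genes that rose and 2441 that fell, and 13 genes had probe sets called both ways. Large differences were mostly rises, with 99 probe sets higher and 3 lower by at least 4-fold, and 544 higher and 226 lower by at least 2-fold. By the size rule, 2543 probe sets differed by at least 1.5-fold without overlap, against 16 and 29 in the other splits of the arrays. Pools did not overlap for 52.7% of probe sets, where chance gives 33.3%, and for 24.8% and 21.6% in the other splits. Each of those splits sets 1 control and 1 social threat pool against the same, so that any difference between the groups lowers its counts, which are therefore no measure of chance. They gave 0 limma calls each, with 746 and 578 probe sets at an unadjusted p under 0.05, against 11837 in the real split. The number of calls fell to 3171 without social threat pool 2, to 3341 without social threat pool 1 and to 4689 without the variance trend.

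**Figure D1:**
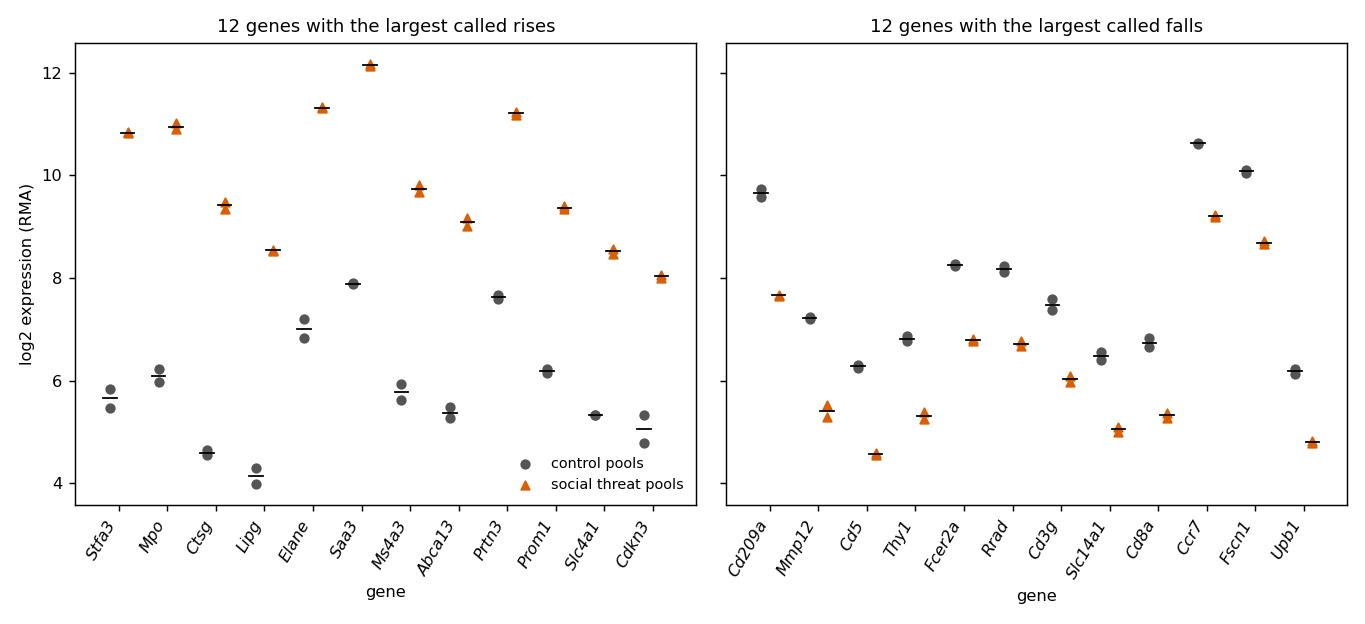
Log2 expression (RMA) of the 12 genes with the largest called rise (left) and the 12 with the largest called fall (right), with 1 point per pool, circles for control, triangles for social threat and a bar at each group mean. The pools of the groups did not overlap for any gene shown, and the differences reached 36.1-fold among the rises (Stfa3) and 3.99-fold among the falls (Cd209a).

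All 19 measured genes of the immature neutrophil granule list rose, also when adjusted over the list alone, with a median log2 fold change of 1.45. Ctsg, the granule protease cathepsin G, rose by 4.81 (SE 0.10) and Elane, neutrophil elastase, by 4.31 (SE 0.10). Prtn3, proteinase 3, rose by 3.58 (SE 0.06), from 7.63 ± 0.05 to 11.21 ± 0.04. Cd177, a neutrophil surface protein, rose by 1.94 (SE 0.03). Genes of secondary granules that were already bright rose less, among them lactoferrin (Ltf), by 1.00 (SE 0.02), and Camp, by 0.68 (SE 0.02), both chosen after their values were seen. Camera gave an adjusted p of 8.89e-36 for this list, and adjusted p = 0.126 with an estimated correlation. Ctsg stood at 4.60 ± 0.07 in the control pools, near the array median, so its fold change of 28.1 rests on a control level that background can set.

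Of the 16 measured mature neutrophil genes, 10 rose and 4 fell, with the same counts adjusted over the list alone and a median of 0.26. Asprv1 rose by 1.18 (SE 0.04), Mmp9, gelatinase B, by 0.58 (SE 0.03) and the formyl peptide receptor Fpr2 by 0.57 (SE 0.03), while Ccrl2 fell by 0.83 (SE 0.03). The list was called higher by camera (adjusted p = 0.000225), with adjusted p = 0.233 with an estimated correlation. Other genes with the largest rises were Stfa3, a stefin, by 5.18 (SE 0.11), the acute phase gene Saa3, by 4.26 (SE 0.05), and Lipg, endothelial lipase, to 8.54 ± 0.01. Ms4a3, a gene of granulocyte progenitors, rose by 3.95 (SE 0.11), Abca13 by 3.71 (SE 0.11) and Prom1, which encodes CD133, by 3.19 (SE 0.08). Lipg stood at 4.14 ± 0.22 in control pools, below the array median, so the size of its rise rests on a level that background can set. Itgam, the antigen used for isolation, rose from 10.74 ± 0.38 to 11.62 ± 0.04 (log2 fold change 0.88, SE 0.13, limma adjusted p = 0.0015), and its control pools stood at 10.47 and 11.01.

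Of the 33 measured cell cycle genes, 31 rose, with a median of 1.86. Adjusted over the list alone, 31 rose and 1 fell. Rrm2, a subunit of ribonucleotide reductase, rose by 2.35 (SE 0.06), from 7.96 ± 0.03 to 10.30 ± 0.00. Mki67, the proliferation antigen Ki-67, rose by 2.25 (SE 0.08), Ube2c by 2.15 (SE 0.07) and Birc5, survivin, by 2.15 (SE 0.08). Cdkn3, a phosphatase of cell cycle kinases that was among the largest rises, rose by 2.96 (SE 0.16). The list was called by camera (adjusted p = 7.07e-36), with adjusted p = 0.112 with an estimated correlation. The median of the immature neutrophil granule list was 1.45 and that of the erythroid list 1.02 in the same pools.

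Of the 15 measured erythroid genes, 10 rose and 0 fell, with the same counts adjusted over the list alone and a median of 1.02. Slc4a1, the band 3 anion exchanger of red cells, rose by 3.19 (SE 0.09), with 2 of its 3 probe sets called, and by 2.10 as the mean of them all. Hemgn rose by 2.79 (SE 0.13), Rhag, a Rhesus-associated membrane protein, by 2.22 (SE 0.12) and carbonic anhydrase 2 (Car2) by 1.93 (SE 0.08). Camera called the list (adjusted p = 3.37e-10), with adjusted p = 0.112 with an estimated correlation. A probe set shared by several beta globin genes, chosen after its values were seen, rose by 0.37 (SE 0.03) from a level of 12.34. Probe sets shared by the alpha globin genes Hba-a1 and Hba-a2 rose by 0.21 to 0.51. The list counts Hba-a1 as not called, by a probe set at 3.88 ± 0.05 in controls. Hemgn and Rhag stood at 3.87 ± 0.18 and 3.43 ± 0.10 in control pools, below the array median, and background can set the size of their rises.

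Platelet and megakaryocyte markers rose for 5 of 12 measured genes and fell for 0, with 6 rises adjusted over the list alone and a median of 0.30. The chemokine genes Ppbp and Pf4 of platelet granules rose by 1.00 (SE 0.08) and 0.89 (SE 0.08), and Gp1bb by 1.69 (SE 0.14), or by 0.93 as the mean of its probe sets, from a control level of 4.71 ± 0.25 that background can set. Camera called the list (adjusted p = 0.000739), with adjusted p = 0.278 with an estimated correlation. The stem and progenitor cell list was not called (adjusted p = 0.906), with 2 rises and 3 falls among 11 genes, the same adjusted over the list alone. Its median was 0.09, its mean 0.00 and its tested direction up. Within it the transcription factor gene Myb rose by 1.04 (SE 0.07) and the receptor gene Kit fell by 0.72 (SE 0.08).

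Conventional dendritic cell markers fell for 10 of 12 measured genes, and for 11 adjusted over the list alone, with a median of -0.90. Cd209a fell by 2.00 (SE 0.07) and Ccr7, a chemokine receptor of migrating dendritic cells, by 1.41 (SE 0.05). Dpp4 fell by 1.36 (SE 0.08) and Itgax, which encodes CD11c, by 0.89 (SE 0.05). Camera called the list (adjusted p = 1.1e-10), with adjusted p = 0.112 with an estimated correlation. Fscn1, the actin-bundling protein fascin, was among the largest falls at -1.39 (SE 0.06), or -0.62 as the mean of its probe sets, as was the macrophage elastase gene Mmp12 at -1.81 (SE 0.11). Of 8 plasmacytoid dendritic cell genes, 3 fell and 0 rose, the same adjusted over the list alone, and the list was not called (median -0.18, adjusted p = 0.0822).

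B cell markers fell for 14 of 16 measured genes and rose for 1, with the same counts adjusted over the list alone and a median of -0.90. Fcer2a, the low-affinity IgE receptor CD23, fell by 1.47 (SE 0.08), Fcmr, the IgM Fc receptor, by 1.35 (SE 0.07) and Cd79b, a chain of the B cell receptor, by 1.21 (SE 0.07). Ighm, the heavy chain of IgM, moved the other way. It rose by 0.60 (SE 0.03), and 7 of its 11 probe sets rose, by 0.31 to 2.52. The list was called lower (camera adjusted p = 6.15e-11), with adjusted p = 0.112 with an estimated correlation. Plasma cell genes were not called as a list (median -0.07, adjusted p = 0.393), with 1 rise and 3 falls among 10 genes, the same adjusted over the list alone. Igha, the heavy chain of IgA, fell by 0.39 (SE 0.03) and Irf4 by 1.15 (SE 0.09).

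T cell markers fell for 11 of 13 measured genes, and for 12 adjusted over the list alone, with a median of -0.76. Cd5 fell by 1.71 (SE 0.11), from 6.28 ± 0.04 to 4.58 ± 0.03, a level near the array median that background can set, so this fall is a minimum. The receptor subunits Cd3g and Cd3d fell by 1.45 (SE 0.11) and 0.96 (SE 0.07). Thy1 and Cd8a were also among the largest falls. Thy1 fell from 6.82 ± 0.08 to 5.32 ± 0.11, and Cd8a fell by 1.41 (SE 0.12) with 3 of 5 probe sets called, or by 0.77 as their mean. Camera called the T cell list (adjusted p = 1.66e-08), with adjusted p = 0.112 with an estimated correlation. NK cell markers fell for 9 of 14 measured genes, and for 12 adjusted over the list alone, with a median of -0.60. The receptor genes Klrk1 and Klrd1 fell by 1.34 (SE 0.08) and 1.28 (SE 0.07), and the chemokine gene Ccl5 by 1.10 (SE 0.04). The NK cell list was called by camera (adjusted p = 3.3e-07), with adjusted p = 0.126 with an estimated correlation.

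**Figure D2:**
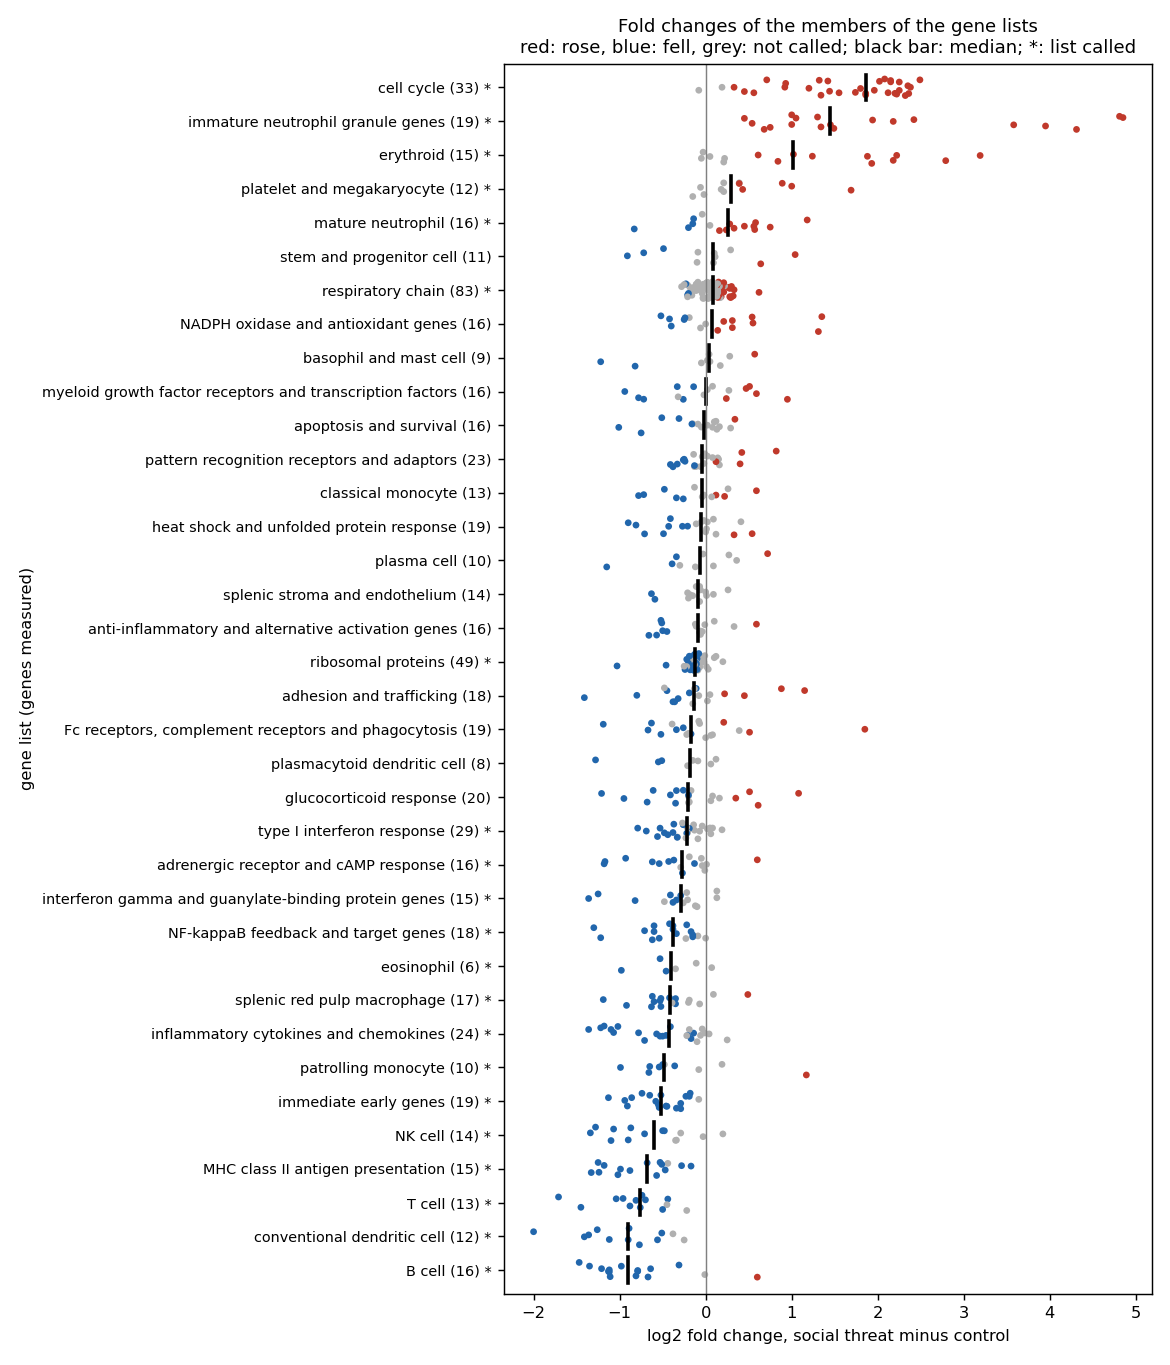
Log2 fold change (social threat minus control) of every measured member of each gene list, with 1 point per gene coloured by its call, a black bar at the list median, the number of measured genes in brackets and an asterisk for lists called by camera at the preset correlation. Medians ran from 1.86 for cell cycle genes to -0.90 for B cell and conventional dendritic cell markers, and no list was called with an estimated correlation.

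Splenic red pulp macrophage markers fell for 11 of 17 measured genes and rose for 1, against 12 falls and 1 rise adjusted over the list alone, with a median of -0.42. Axl, a receptor for apoptotic cells, fell by 1.19 (SE 0.06), or by 0.65 as the mean of its probe sets, Hpgd by 0.92 (SE 0.05), Apoe by 0.62 (SE 0.04) and the complement gene C1qa by 0.60 (SE 0.04). The list was called lower (camera adjusted p = 4.41e-08), with adjusted p = 0.278 with an estimated correlation. Patrolling monocyte genes fell for 6 of 10 and rose for 1, against 8 falls and 1 rise adjusted over the list alone, with a median of -0.49. Eno3 fell by 0.99 (SE 0.06) and Nr4a1, which patrolling monocytes require, by 0.54 (SE 0.04), while Pglyrp1, a peptidoglycan recognition protein also stored in neutrophil granules, rose by 1.17 (SE 0.03). Camera called that list (adjusted p = 0.00193), with adjusted p = 0.278 with an estimated correlation. Classical monocyte genes went both ways, with 3 rises and 5 falls among 13, or 5 and 6 adjusted over the list alone, and were not called (median -0.04, adjusted p = 0.305). Chil3 rose by 0.59 (SE 0.03), while the transcription factor genes Irf8 and Klf4 fell by 0.78 (SE 0.06) and 0.72 (SE 0.04).

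Eosinophil markers fell for 3 of 6 measured genes, and for 4 adjusted over the list alone, with a median of -0.40. Ccr3, the eotaxin receptor, fell by 0.98 (SE 0.09). The list was called (camera adjusted p = 0.0222), with adjusted p = 0.278 with an estimated correlation. Basophil and mast cell genes were not called as a list (adjusted p = 0.864), with 1 rise and 2 falls among 9 genes, or 2 of each adjusted over the list alone. Their median of 0.04 and tested direction up stood against a mean of -0.11. Genes of splenic stroma and endothelium were not called (median -0.09, adjusted p = 0.197), with 2 falls among 14 genes, the same adjusted over the list alone. The scavenger receptor gene Stab2 was among them and fell by 0.63 (SE 0.08).

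Of 24 inflammatory cytokine and chemokine genes, 16 fell and 0 rose, the same adjusted over the list alone, with a median of -0.43. Cxcl9 fell by 1.36 (SE 0.07), Ccl4 by 1.02 (SE 0.05) and Ptgs2, the inducible cyclooxygenase, by 0.78 (SE 0.04). Il6 fell from 6.19 ± 0.34 to 4.97 ± 0.01 (log2 fold change -1.22, SE 0.16, limma adjusted p = 0.000618). Its control pools stood at 6.43 and 5.95, and its level under social threat was near the array median, where background can limit the fall. Il1b fell by 0.14 (SE 0.03) from a level of 13.20 ± 0.05, a small difference (limma adjusted p = 0.00546). Without the variance trend its adjusted p was 0.348, without social threat pool 1 it was 0.0702 and without social threat pool 2 it was 0.0606. Tnf stood at 9.90 ± 0.10 and 9.86 ± 0.00 and was not called (adjusted p = 0.731). The cytokine list was called lower by camera (adjusted p = 3.37e-10), with adjusted p = 0.112 with an estimated correlation. The medians of the B cell, T cell, NK cell and conventional dendritic cell markers were -0.90, -0.76, -0.60 and -0.90, and Ccl5, a member that fell, also stands in the NK cell list.

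Of 18 NF-kappaB feedback and target genes, 15 fell and 0 rose, with 17 falls adjusted over the list alone and a median of -0.38. The adaptor gene Traf1 fell by 1.30 (SE 0.07), Cd83, a surface protein of activated dendritic cells and B cells, by 1.22 (SE 0.04) and the inhibitor gene Tnfaip3 by 0.60 (SE 0.04). Camera called this list (adjusted p = 1.34e-11), with adjusted p = 0.128 with an estimated correlation. Immediate early genes fell for 18 of 19, the same adjusted over the list alone, with a median of -0.52. Among these transcription factor genes Egr2 fell by 1.13 (SE 0.05), Egr1 by 0.94 (SE 0.04) and Atf3 by 0.91 (SE 0.04), the last from 11.67 ± 0.01 to 10.76 ± 0.03. They too were called as a list (camera adjusted p = 1.73e-16), with adjusted p = 0.112 with an estimated correlation. In the same pools the medians of the B cell, T cell and conventional dendritic cell markers were -0.90, -0.76 and -0.90.

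MHC class II antigen presentation genes fell for 14 of 15, and for 15 adjusted over the list alone, with a median of -0.68. H2-Ab1, a class II beta chain, fell by 0.88 (SE 0.02), from 13.10 ± 0.01 to 12.22 ± 0.00. H2-Oa and H2-DMa, which act in peptide loading, fell by 1.33 (SE 0.06) and 0.99 (SE 0.04). Camera called the class II list (adjusted p = 1.09e-16), with adjusted p = 0.112 with an estimated correlation. The B cell and conventional dendritic cell marker lists, whose cells carry class II, both had medians of -0.90.

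Type I interferon response genes fell for 13 of 29 and rose for 0, against 16 falls and 1 rise adjusted over the list alone, with a median of -0.22. The antiviral gene Mx1 fell by 0.79 (SE 0.08), Bst2, tetherin, by 0.69 (SE 0.07) and Irf7 by 0.48 (SE 0.05). The list was called lower (camera adjusted p = 5e-06), with adjusted p = 0.126 with an estimated correlation. Of 15 interferon gamma and guanylate-binding protein genes, 7 fell and 0 rose, with 11 falls adjusted over the list alone and a median of -0.29. Ciita, the class II transactivator, fell from 6.77 ± 0.13 to 5.52 ± 0.03, or by 0.83 as the mean of its probe sets, and Irf1 fell by 0.41 (SE 0.04). Camera called these genes (adjusted p = 6.41e-05), with adjusted p = 0.241 with an estimated correlation. The median of the plasmacytoid dendritic cell markers was -0.18 and that of the B cell markers -0.90.

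Glucocorticoid response genes went both ways, with 4 rises and 9 falls among 20, or 4 and 11 adjusted over the list alone, and the list was not called (median -0.20, adjusted p = 0.0871). Fkbp5, a chaperone induced by glucocorticoids, rose from 7.41 ± 0.00 to 8.50 ± 0.05 (log2 fold change 1.08, SE 0.08, limma adjusted p = 1.48e-05), with 2 of 3 probe sets called. The annexin gene Anxa1 rose by 0.61 (SE 0.03) and Cebpd by 0.51 (SE 0.05), while the phosphatase gene Dusp1 fell by 0.34 (SE 0.02). Larger falls in the list, chosen after their values were seen, were those of Ddit4 (-1.21), Per1 (-0.95) and Zbtb16 (-0.68). As means of all probe sets of each gene, the rises were 0.59 for Fkbp5, 1.23 for Anxa1 and 0.27 for Cebpd, all still called. Nr3c1, the glucocorticoid receptor, stood at 9.83 ± 0.13 and 9.63 ± 0.09 and was not called by its brightest probe set (log2 fold change -0.20, SE 0.07, limma adjusted p = 0.106). Of its 6 probe sets, 1 dimmer probe set was called and rose by 0.45 (SE 0.09). Without control pool 2 the brightest probe set passed, at an adjusted p of 0.0131, where the omission of the other pools gave 0.187 to 0.570. With the pool number as a block the brightest probe set passed too (limma adjusted p = 0.0233). The mean of all probe sets of Nr3c1 was 0.06, of the opposite sign and not called (adjusted p = 0.579).

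Adrenergic receptor and cAMP response genes fell for 9 of 16 and rose for 1, against 10 falls and 1 rise adjusted over the list alone, with a median of -0.28. The genes that fell furthest were Crem, a regulator of cAMP-driven transcription, by 1.18 (SE 0.07), and the orphan receptor genes Nr4a3, by 1.17 (SE 0.05), and Nr4a2, by 0.93 (SE 0.07). For each of these some probe sets were not called, and as means of all probe sets the falls were -0.70, -0.50 and -0.60. Camera called the list (adjusted p = 9.99e-05), with adjusted p = 0.241 with an estimated correlation. The B, T, NK and conventional dendritic cell markers together had a median of -0.81, and the patrolling monocyte list, which shares Nr4a1 with this list, a median of -0.49. Nr4a1 also stands in the immediate early list, which had a median of -0.52.

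Ribosomal protein genes fell for 28 of 49 and rose for 0, with 31 falls adjusted over the list alone, by a median of only -0.12. Rpl12 fell furthest, by 1.03 (SE 0.13), at a level far below the list median of 12.72. Camera called the family lower (adjusted p = 4.41e-08), with adjusted p = 0.233 with an estimated correlation. Respiratory chain genes rose for 22 of 83 and fell for 3, or 30 and 6 adjusted over the list alone, with a median of 0.08. Ndufv3 rose by 0.62 (SE 0.05). That family was called higher (camera adjusted p = 0.000755), with adjusted p = 0.481 with an estimated correlation, and fry gave an adjusted p of 0.108. In the same pools the medians were -0.90 for B cell, -0.76 for T cell and -0.90 for conventional dendritic cell markers, and 1.45 for immature neutrophil granule genes.

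The remaining lists were not called and held members that moved both ways. NADPH oxidase and antioxidant genes had 8 rises and 5 falls among 16, or 8 and 6 adjusted over the list alone (median 0.07, camera adjusted p = 0.0578), and the list was called in 4 of 12 alternative settings (adjusted p from 0.00397 to 0.414). Gclm, a subunit of the first enzyme of glutathione synthesis, rose by 1.35 (SE 0.07) and the oxidase subunit genes Ncf1 and Ncf4 by 0.55 (SE 0.03) and 0.54 (SE 0.03). Adhesion and trafficking genes had 4 rises and 8 falls among 18, or 4 and 12 adjusted over the list alone (median -0.14, adjusted p = 0.0773), and S1pr4 rose by 1.15 (SE 0.07). Fc receptor, complement receptor and phagocytosis genes had 3 rises and 7 falls among 19, or 4 and 9 adjusted over the list alone (median -0.17, adjusted p = 0.0822). Among them the scavenger receptor gene Marco rose by 1.85 (SE 0.06) and Cd36 fell by 0.67 (SE 0.06). Pattern recognition receptors and adaptors had 4 rises and 7 falls among 23, the same adjusted over the list alone (median -0.04, adjusted p = 0.864), and the adaptor gene Tirap rose by 0.82 (SE 0.07).

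Anti-inflammatory and alternative activation genes had 1 rise and 6 falls among 16, or 2 and 6 adjusted over the list alone (median -0.09, adjusted p = 0.0534). In 6 of 12 alternative settings the list was called lower, with adjusted p over all 12 from 0.0111 to 0.314. Mrc1, the mannose receptor, fell by 0.52 (SE 0.06) and Tgfb1 by 0.45 (SE 0.05). Heat shock and unfolded protein response genes had 2 rises and 8 falls among 19, or 3 and 9 adjusted over the list alone (median -0.05, adjusted p = 0.0628), and the list was called in 4 of 12 alternative settings (adjusted p from 0.0127 to 0.3). The heat shock genes Hspa1a and Hspa1b fell by 0.90 (SE 0.09) and 0.81 (SE 0.08). Myeloid growth factor receptors and transcription factors had 5 rises and 6 falls among 16, or 5 and 7 adjusted over the list alone (adjusted p = 0.837), with a median of 0.00, a mean of -0.02 and tested direction down. Apoptosis and survival genes had 1 rise and 5 falls among 16, or 2 and 5 adjusted over the list alone (median -0.02, adjusted p = 0.368), and Bcl2 fell by 0.75 (SE 0.08) with 3 of 5 probe sets called. The other genes among the largest falls were Rrad (-1.46, SE 0.09), Slc14a1 (-1.43, SE 0.12) and Upb1 (-1.37, SE 0.11), the last down to 4.81 ± 0.03, where background can limit the fall.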

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

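All alternatives in this part were fixed before the data were examined. The count of 7099 called probe sets was 4689 without the variance trend, and between 3171 (without social threat pool 2) and 8721 (without control pool 2) when a pool was left out. A fit with 1 pool in a group assumes that this pool varies like the other group, and it has fewer samples. The cause of the change without a trend was not tested. No probe set called in both fits changed direction under any of these settings, and the share of calls that were higher stayed between 43.4% and 51.1%. By the size rule, the count of 2543 was 776 at 2-fold and 7140 at the looser threshold tried, thresholds that admit fewer and more probe sets by construction. It was 1372 with 1 probe set per gene, where fewer features are counted, and between 2626 and 3070 when a pool was left out. Camera called 21 lists at the preset correlation, 0 with an estimated correlation, 30 lists passed fry, and 22 to 25 were called when a pool was left out. The estimated correlations come from 4 arrays. The B cell, T cell and conventional dendritic cell lists lost their calls with estimated correlations of -0.021, -0.031 and -0.027, below the preset one. A higher correlation between genes is therefore not what ended those calls. In simulated data drawn without correlation, the camera adjusted p of the shifted list also went from 1.13e-283 at the preset correlation to 0.0208 with an estimated one. Such a change can therefore arise where genes do not correlate, and an adjusted p with an estimated correlation does not measure correlation alone. What caused the change was not tested further. Of the lists that were not called, 10 were called under at least 1 alternative, 6 of them by an alternative other than fry. These 6 were the anti-inflammatory, heat shock, NADPH oxidase, adhesion, Fc receptor and plasmacytoid dendritic cell lists. Of 153 named genes, 125 had the same call under every setting run on them, and of 36 lists 5 did. Calls of named genes ended for 12 without social threat pool 1, for 9 without social threat pool 2, for 2 without control pool 1 and for 1 without control pool 2, and for 15 without the trend. The mean of all probe sets of a gene ended the calls of 4 named genes. Signal over background limits the dim genes, whose fold changes RMA compresses.

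Both groups carry pool numbers 1 and 2, and no label says that a number marks a shared day or litter. The deviations of same-numbered pools correlated at 0.052 over all probe sets. With the pool number as a replicate block, 8168 probe sets and 21 lists were called, and of the named genes 1 changed its call, Nr3c1, with an adjusted p of 0.0233 against a range of 0.0131 to 0.579 over its alternatives.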

Other observations

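All tests in this part were chosen after the results were seen. Among 4 gene groups picked in that way, the GIMAP family, small GTPases of lymphocytes, fell for 7 of 8 genes with a median of -1.01 (camera adjusted p = 1.19e-07, and adjusted p = 0.0607 with an estimated correlation). Gimap6 fell by 1.32 (SE 0.07) and Gimap3 by 1.07 (SE 0.09), where the B and T cell markers had medians of -0.90 and -0.76. Centromere protein genes rose for 15 of 21 with a median of 0.91 (camera adjusted p = 3.66e-13, and adjusted p = 0.0586 with an estimated correlation), led by Cenpf at 2.13 (SE 0.10) and Cenpk at 1.96 (SE 0.11).

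Haem synthesis genes rose for 3 of 8 with a median of 0.24 (camera adjusted p = 0.000251, and adjusted p = 0.194 with an estimated correlation). Alas2, the erythroid form of the first enzyme, rose by 0.84 (SE 0.08), and Alas1, the form of other cells, by 0.74 (SE 0.05). Cholesterol synthesis genes went both ways, with 8 rises and 3 falls among 17 and a median of 0.19 (camera adjusted p = 0.0155, and adjusted p = 0.228 with an estimated correlation). Fdps rose by 1.28 (SE 0.06) while Cyp51 fell by 0.45 (SE 0.08). A probe set shared by Apol7a, Apol7c and Gm8221 had a fall of -2.31 (SE 0.08) and a probe set shared by Apol7c and Gm8221 a fall of -2.27 (SE 0.09), beyond that of any gene named alone. Another, shared by Apol7e and Apol7b, stood at -0.30 (SE 0.11) and was not called (adjusted p = 0.117), and a probe set shared by Stfa1 and Cstdc5 rose by 2.89 (SE 0.10).

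Immature neutrophil granule genes rose further than mature neutrophil genes. Bright probe sets lose range near the top of the scale, but among genes with control levels between 9 and 13 the medians were still 1.00 for 9 granule genes and 0.30 for 14 mature genes. That difference of 0.70 argues against a ceiling as the whole cause (two-sided permutation p = 0.00472 over genes with 100000 permutations, 0.0189 adjusted over 4 such tests), although genes are not independent replicates and the mature genes were brighter there (median 11.82 against 11.01). A hypothesis that remains open is a larger share of neutrophil precursors at a dividing stage. The cell cycle median of 1.86 was known before this was posed, so it is no test of it, and dividing erythroid cells could give it too. Isolation by CD11b should remove most erythroid cells, but erythroid RNA was present. A probe set shared by Hba-a1 and Hba-a2, alpha globin genes, stood at 13.21 in controls and rose by 0.21, and 10 of 15 erythroid genes rose.

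Markers of B cells, T cells, NK cells and conventional dendritic cells had a median of -0.81 over 55 genes, of which 44 fell, 10 were not called and 1, Ighm, rose, and 2 are also held by another fixed list. Isolation by CD11b should remove most T cells, and 5 of these markers stood at 10 or above in controls, among them Ighm (12.62), which rose by 0.60, and Ccl5 (11.24) and Ccr7 (10.62), which fell. A single dilution of every cell type other than neutrophils would lower red pulp macrophage markers alike. Their median was -0.42 over 17 genes, a difference of 0.39 (two-sided permutation p = 0.0157 over genes, adjusted 0.0314). The medians go against such a dilution as the whole cause, but the p-value cannot decide it. Genes are not independent replicates, and the red pulp list had an estimated correlation of 0.443. The sets also differed in level, with control medians of 10.23 for red pulp and 7.69 for the other markers. Erythroid genes, which such a dilution would also lower, rose for 10 of 15 with 0 falls (median 1.02). That argues against it for erythroid cells, although many of these genes were dim (control median 4.76). Classical monocyte genes went both ways (median -0.04), while the patrolling monocyte and eosinophil lists were called lower, with medians of -0.49 and -0.40. Fewer lymphoid and dendritic cells in the isolated fraction may underlie the 44 falls, but the rise of Ighm is not what it alone would give. B and T cell medians differed by -0.13 (permutation p = 0.377), and lower expression per cell cannot be told apart from fewer cells on pooled RNA.

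Immediate early genes, which cell isolation can also induce, fell in the social threat pools. A weaker handling response could lower heat shock genes too. The median of 6 cytosolic heat shock genes was -0.13, with 3 of them falling. It lay between the limits set for a fall and for none, which leaves this explanation open. Less RNA from lymphoid and dendritic cells may also contribute. Immediate early genes fell less than the markers of these cells, by a difference of 0.29 (two-sided permutation p = 0.0484 over genes, adjusted 0.0645). This is no evidence for that explanation, since only a larger fall would have counted against it. A fall within neutrophils cannot be told apart from it. An effect of social threat on these genes within a cell type was not tested.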
